A study of Mus musculus with 18 samples.

How the data were processed

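Total RNA from whole, undissociated dorsal root ganglia was sequenced from wild-type C57BL/6 mice and mice homozygous for a Tmem184b gene trap on that background, per the labels. The genotype and age labels define 6 groups of 3 libraries, at E13.5, P0 and P10, and the replicate names come from the sample titles. The labels do not say that each library came from a separate animal or litter, so p-values measure the spread between libraries. No label gives a sequencing batch or date.

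The authors quantified reads with Salmon 0.11.1 on the mm10 build, per the submitters' processing notes, and deposited estimated counts of reads per transcript with effective lengths. Those notes also name DESeq2 without a version. The transcript annotation, trimming and strand setting are not given in the sources used here. Salmon divides reads that match several transcripts by a model, so genes with near-identical copies can gain or lose reads to each other, and a strain variant can move reads from a gene to its pseudogene. Without a known strand setting, antisense partners cannot be told apart.

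The table held 134961 transcript lines with values, 6 further lines had been emptied, and 0 columns belonged to other samples. Estimated counts were summed to 53090 genes by Ensembl gene ID and rounded to whole numbers. Positions and symbols came from GENCODE M21 on GRCm38 for 53023 genes. Totals ran from 17.1 to 80.6 M reads per library with a median of 28.8 M. Counting error is small at this depth for all but scarce genes, and intervals and floors cover counting error only, since reads carry no molecular identifiers. Where every library of a group had no read, a floor of 3 reads over the group gave a lower bound. No pair of libraries within a group was as alike as sampling noise alone would make it: the lowest chi-square per gene was 6.2, so all 18 were kept as separate.

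Gene counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, and a robust quasi-likelihood F test in one model of 6 group means with 12 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over 21051 genes. SEs were derived from the fold change and F. Mutants were set against wild types at each age and averaged over ages, the difference of the effect between ages was tested jointly, and wild types were compared between successive ages. Before the data were examined, 42 lists of genes were fixed (sensory neuron classes, excitability and synapse, signalling, glia, other tissues, technical markers); 1332 of 1335 entries matched a gene. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Lists called with the preset and with the estimated correlation numbered 22 and 1 at E13.5, 20 and 1 at P0, 15 and 0 at P10, 25 and 2 averaged over ages, 26 and 7 for wild type P0 against E13.5, and 26 and 0 for wild type P10 against P0. The lists were not all disjoint, and the ganglion itself expresses some genes of most other-tissue lists.

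Genes were named by a rule fixed beforehand. For each genotype comparison these were called genes with an average log2 CPM of at least 1 whose mutant libraries all lay on one side of the wild types: the 10 highest, the 10 lowest and the 8 with the smallest p. Averaged over ages, the sign had to be shared by all 3 ages. The joint test named the 8 with the smallest p, and each described list up to 4 members with the smallest p. Predicted gene models were not named by the rule, and those given here were chosen after their values were seen. Shared sequence was measured as the percent of a gene's 31-base words found in other genes, over 219 genes, of which 25 shared at least 50%.

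The test was also tested on simulated data. It found 71.6% of 2-fold changes at E13.5 (20357 genes in the step), 70.1% at P0 (20343 genes) and 76.1% at P10 (20322 genes), and 41.8%, 47.8% and 50.7% of 1.5-fold changes. Each share is of 67 changed genes, drawn only from genes with a mean above 1 CPM, so scarcer genes are not covered. At most 5.37% of calls were false, in the averaged comparison (20308 genes). The list test called the 1 shifted list and 0 of the others in each comparison. Genes were simulated independently of each other, so this cannot show how the preset correlation behaves where list members vary together. In the data the estimated correlation reached 0.89, for ribosomal protein genes at E13.5. The simulation also gave 150 calls at E13.5, against 5880 in the data.

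Alternatives planned beforehand were RLE scaling, no and stricter low-count filters, transcript length offsets, limma-voom, DESeq2 1.42.0, Y-linked expression as a covariate, the compared ages alone, each library left out in turn, other set tests and windows, and a block of replicate letters. Added after the data were seen were leaving out the libraries labelled wild type P10 C and E, libraries of a single sex, E13.5 and P0 alone, mutant age changes, and a spinal cord covariate. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.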

Results

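Whole dorsal root ganglia, the clusters of sensory neurons and glia beside the spinal cord, were profiled by RNA sequencing from wild-type C57BL/6 mice and from mice homozygous for a gene-trap allele of Tmem184b, which encodes a transmembrane protein. Ganglia were taken from E13.5 embryos, on the day of birth (P0) and at postnatal day 10 (P10). Each combination of genotype and age had 3 libraries, 18 in all. The series title places the question in development, so mutants were set against wild types at each age, and wild types of successive ages against each other. The libraries held 17.1 to 80.6 M estimated reads, with a median of 28.8 M, and 21051 genes had enough reads to be tested. The deepest library was mutant E13.5 1 and the shallowest was the library labelled wild type P10 C. Levels are given as CPM, which are read counts scaled to library size, as mean ± SD with n = 3, and fold changes are mutant against wild type on the log2 scale with their standard error (SE).

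Tmem184b (ENSMUSG00000009035) lies on the minus strand of chromosome 15 from 79360684 to 79403569 in GRCm38. In the 3 wild-type E13.5 libraries it stood at 55.9, 57.4 and 56.7 CPM, and in the 3 wild-type P0 libraries at 50.8, 42.7 and 47.9 CPM. The mutants held 1.49, 1.24 and 2.22 CPM at E13.5, 2.83, 2.51 and 1.86 CPM at P0, and 2.21, 1.91 and 3.33 CPM at P10. At P10 this gene went against the labels of 2 libraries. The library labelled wild type P10 1 held 80.1 CPM, whereas the library labelled wild type P10 C held 4.16 CPM and the library labelled wild type P10 E held 1.91 CPM. Both lay within or near the range of the mutants. Tmem184b was lower in mutants by a log2 fold change of -5.12 (SE 1.08, edgeR adjusted p = 0.00368) at E13.5 and of -4.29 (SE 1.03, adjusted p = 0.00816) at P0. These SEs come from a spread fitted over all groups, including the libraries labelled wild type P10 at 80.1, 4.16 and 1.91 CPM. A planned edgeR fit used only the libraries of the compared age. It gave -5.14 (adjusted p = 2.64e-06) at E13.5 and -4.3 (adjusted p = 3.59e-08) at P0. In E13.5 mutants 34.9, 14.76 and 26.65 reads lay on a 625-base retained-intron transcript, against 0, 0 and 4.4 in wild types. Its part in the next values was not tested. With average transcript length offsets the Tmem184b log2 fold change at E13.5 was -2.62 (adjusted p = 0.0521) and the Tmem184b log2 fold change at P0 was -2.08 (adjusted p = 0.0896), so neither passed. At P10 the value was -3.54 (SE 1.02, adjusted p = 0.458) with all libraries and -4.98 (adjusted p = 1.53e-09) with the libraries labelled C and E left out, a comparison added after their levels were seen. With 9 libraries a side and the ages averaged it was -4.31 (SE 0.6, adjusted p = 0.000568). Every direction drawn at P10, averaged over ages, between ages or between wild-type P10 and P0 therefore rests on 2 libraries whose label this gene goes against.

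**Figure D1:**
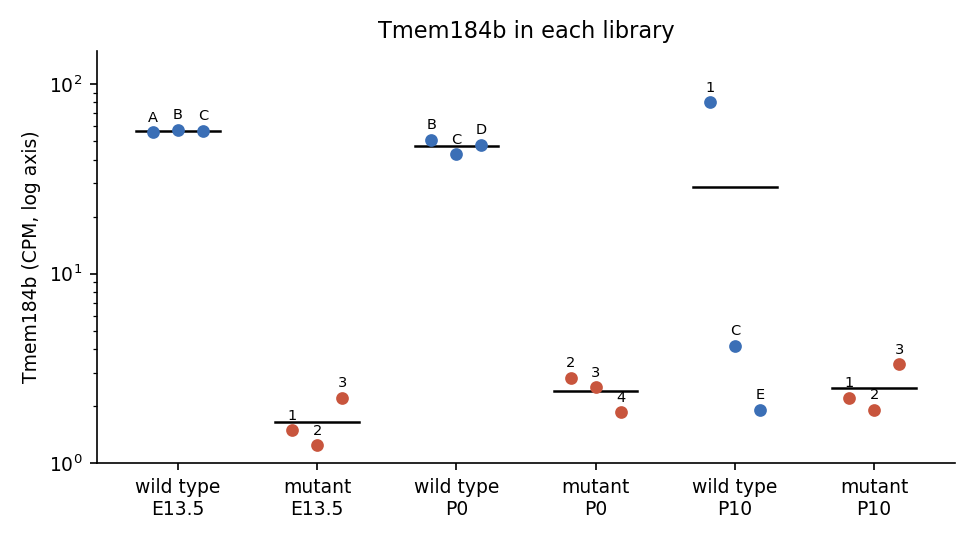
Tmem184b in each library, in CPM on a log axis, by genotype and age. Points are libraries with their replicate name and the line is the group mean. The mutants sit between 1.24 and 3.33 CPM, and the libraries labelled wild type P10 C and E sit at 4.16 and 1.91 CPM while the other 7 wild types sit between 42.7 and 80.1 CPM.

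At E13.5 the mutant ganglia carried more transcript of genes that neurons use to fire and to release transmitter, and less of the genes of dividing cells. The channel, synaptic and cell cycle lists lost their call with an estimated correlation (adjusted p = 0.0974, 0.0974 and 0.123). Embryonic forms made up 74.4% of beta-like globin reads in these wild types and 36.8% in these mutants. Mean fragment length also differed, at 260 and 274 bases. Embryo stage and library source were therefore not separated from genotype. Scn9a, a voltage-gated sodium channel of pain-sensing neurons, rose by 0.96 (SE 0.11, adjusted p = 3.51e-06), and the potassium channel gene Kcna4 by 2.07 (SE 0.23, adjusted p = 2.91e-06). Syt1, the calcium sensor of synaptic vesicle release, rose by 0.97 (SE 0.1), and Rims1 and Rims2, scaffold genes of the release site, by 1.01 (SE 0.11) and 0.91 (SE 0.1). Mcm7, part of the helicase that opens DNA for replication, had a fold change of -1 (SE 0.1, adjusted p = 1.87e-06), and Aurka, a mitotic kinase, one of -1.14 (SE 0.13, adjusted p = 3.54e-06). Of Mcm7, 33.4% of the sequence is shared with other genes, most with Gm5487, so its value is uncertain. Of the 21051 genes, 5880 passed the threshold, 3279 higher and 2601 lower in mutants, and 1563 of them changed at least 2-fold.

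Among the channel genes for sodium and potassium, 35 of 45 tested members rose, 2 fell and 8 did not pass (38 passed when adjusted over the list alone). Their median was 0.69 and the list stood apart from other genes (camera adjusted p = 1.48e-14, but adjusted p = 0.0974 with an estimated correlation). Scn3b, an accessory sodium channel subunit, rose by 0.74 (SE 0.09). Synaptic vesicle and release genes rose in 23 of 35 cases and fell in 0 (24 adjusted over the list alone), with a median of 0.57 and an adjusted p of 2.57e-15, or adjusted p = 0.0974 with an estimated correlation; Syt7 rose by 1.43 (SE 0.15). Pan-neuronal genes had 15 of 26 members higher and 1 lower (18 adjusted over the list alone), a median of 0.34 and an adjusted p of 1.98e-09, or adjusted p = 0.0974 with an estimated correlation. Cell cycle genes fell in 39 of 44 cases and rose in 0 (42 adjusted over the list alone), with a median of -0.81 and an adjusted p of 5.67e-23, or adjusted p = 0.123 with an estimated correlation. Rrm1, which makes deoxynucleotides, and Tpx2, a spindle assembly factor, had fold changes of -0.84 (SE 0.09) and -0.99 (SE 0.12).

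Some members of 3 sensory neuron lists were higher in the same libraries, though these lists lost their call with an estimated correlation. In the non-peptidergic nociceptor list 13 of 26 members rose and 1 fell (16 adjusted over the list alone; adjusted p = 6.75e-05, and adjusted p = 0.385 with an estimated correlation), with a median of 0.4. Ret, a receptor for growth factors of the GDNF family, rose by 1.16 (SE 0.16), its co-receptor gene Gfra2 by 1.14 (SE 0.13) and Cd55 by 1.25 (SE 0.13). In the peptidergic nociceptor list 10 of 23 rose and 3 fell (13 adjusted over the list alone; adjusted p = 0.00303, and adjusted p = 0.0974 with an estimated correlation), with a median of 0.19. Adcyap1, which encodes the neuropeptide PACAP, went from 12.9 ± 0.881 to 30 ± 2.42 CPM, a change of 1.21 (SE 0.08, adjusted p = 9.89e-09), and Tac1, which encodes substance P, from 1.89 ± 0.676 to 7.24 ± 0.862 CPM. The large-diameter mechanoreceptor and proprioceptor list had 16 of 32 members higher and 3 lower (22 adjusted over the list alone; adjusted p = 5.85e-05, and adjusted p = 0.206 with an estimated correlation), with a median of 0.42; Pvalb, which encodes the calcium buffer parvalbumin, rose by 1.94 (SE 0.22) and the transcription factor gene Etv1 by 1.3 (SE 0.14). Glial genes were higher too. In the immature Schwann cell and satellite glia list 16 of 33 rose and 3 fell (22 adjusted over the list alone), with a median of 0.51, and this was the only E13.5 list called with both correlations (adjusted p = 5.09e-09, and adjusted p = 0.0157 with an estimated correlation). Its members Ngfr, the low-affinity neurotrophin receptor gene, and Cadm2, a cell adhesion gene, rose by 1.24 (SE 0.09) and 1.64 (SE 0.12).

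Among genes that met the naming rule, the small p-values at E13.5 included those of March4, a ubiquitin ligase gene, which went from 3.73 ± 0.652 to 25.4 ± 4.27 CPM (2.76, SE 0.15, adjusted p = 6.07e-10), and of Cemip, a hyaluronan-degrading protein gene, from 2.06 ± 0.602 to 17.1 ± 3.47 CPM (3.04, SE 0.19). Prdm8, a transcriptional repressor gene, rose from 12.5 ± 2.64 to 73.4 ± 7.09 CPM (2.55, SE 0.16), and Fbln5, an elastic fibre protein gene, rose by 2.09 (SE 0.15). Among the large decreases named by rule were those of the transcription factor gene Msx1 (-3.44, SE 0.54), from 14.8 ± 4.45 to 1.41 ± 1.31 CPM, and the ligand gene Wnt7b (-3.53, SE 0.8), from 7.53 ± 9.04 to 0.643 ± 0.203 CPM. Without wild type A the Wnt7b log2 fold change at E13.5 was -1.87 (adjusted p = 0.0158), so its size rests largely on 1 library. Rec8, a cohesin subunit of meiosis, and Wdr66 had fold changes of -3.39 (SE 0.58) and -2.82 (SE 0.29). Several of the largest increases came from genes without a read in the 3 wild types. Against a floor of 3 reads over the group, Eif4ebp3 was at least 180-fold and Mrgprx1, an itch receptor gene of later sensory neurons, at least 6.34-fold higher, while Afp, a fetal liver and yolk sac protein, stood at 9.48 ± 8.61 CPM against 1 read in all wild types. Of Eif4ebp3, 66.4% of the sequence is shared with other genes, so its value is uncertain.

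Markers of other tissue and measures of the libraries moved with genotype at E13.5. The mean fragment length, derived from effective lengths, was 260 ± 3.35 bases in wild types and 274 ± 3.84 in mutants (262 ± 1.39 and 272 ± 6.44 at P0), and the ribosomal RNA gene Rn18s-rs5 took 2.63% ± 1.96 of wild-type and 0.32% ± 0.0436 of mutant reads. Haemoglobin transcripts took 6.06% ± 2.54 of the reads in mutants and 0.673% ± 0.266 in wild types, and 14 of 19 erythroid genes rose while 0 fell (15 adjusted over the list alone; adjusted p = 1.47e-08, and adjusted p = 0.223 with an estimated correlation). Skeletal muscle genes had a median of 2.77, or 2.66 with a member absent from the wild types at its bound, with 10 of 33 higher and 1 lower (18 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.709 with an estimated correlation). The muscle level varied between mutant libraries, with the embryonic myosin gene Myh3 at 35 ± 46.6 CPM against 1.69 ± 0.949 CPM, and Myod1, which directs muscle fate, up by 4.35 (SE 1.02). Spinal cord and central glia genes had 1 of 32 members higher and 7 lower, with a median of -0.82 (8 adjusted over the list alone; adjusted p = 0.0268, and adjusted p = 0.567 with an estimated correlation). Endothelial and mural cell genes fell in 13 of 27 cases and rose in 0 (16 adjusted over the list alone; adjusted p = 0.000329, and adjusted p = 0.441 with an estimated correlation), with Cldn5, a tight junction gene of vessels, at -1.38 (SE 0.25). Cytosolic ribosomal protein genes fell in 45 of 69 cases and rose in 0, with a median of -0.5 (52 adjusted over the list alone; adjusted p = 8.82e-16, and adjusted p = 0.441 with an estimated correlation). Rps7 was lowest at -4.54 (SE 0.21), but 30.6% of its sequence is shared with other genes, most with the pseudogene Gm6472, so its level is uncertain. Summed with Gm6472 it stood at 1050 ± 283 CPM in wild types and 513 ± 33.7 CPM in mutants. All 3 wild types of this age carried Y-linked transcripts, as did mutant 3, while mutants 1 and 2 carried Xist at 303 and 255 CPM. Mutant 3 also held 8.91 CPM of Xist, against at most 0.564 CPM in the wild types, so it is not a clean library of a single sex. With mutant 3 alone against the wild types, and the other groups supplying its spread, 1336 genes passed.

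**Figure D2:**
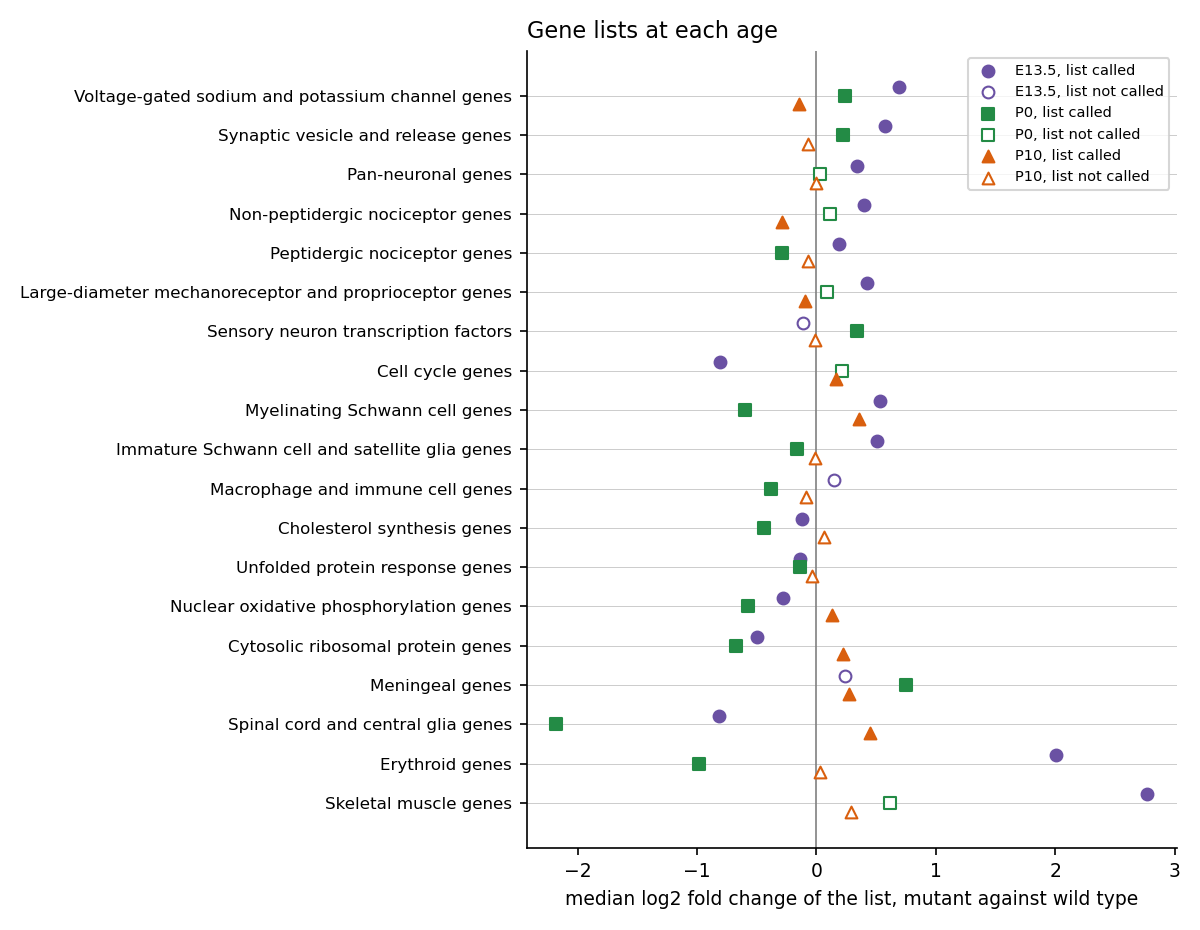
Median log2 fold change, mutant against wild type, of 19 gene lists at E13.5, P0 and P10. Filled symbols are lists called by camera with the preset correlation at an adjusted p under 0.05 and open symbols are lists not called. Synaptic vesicle and release genes sit at 0.57, cell cycle genes at -0.81 and skeletal muscle genes at 2.77 at E13.5, and spinal cord and central glia genes sit at -2.18 at P0.

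At birth the mutant ganglia carried less transcript of cholesterol synthesis genes, the only P0 list whose call held with an estimated correlation. Many oxidative phosphorylation, ribosomal protein and spinal cord genes, and some myelin and macrophage genes, were lower too. These lists lost their call with an estimated correlation (adjusted p = 0.474, 0.474, 0.16, 0.646 and 0.572). Mean fragment length was 262 bases in P0 wild types and 272 in P0 mutants. Neither library source nor the level of spinal cord genes was separated from genotype at this age. Mvd, an enzyme of the mevalonate part of cholesterol synthesis, and Dhcr7, its last step, had fold changes of -1 (SE 0.1, adjusted p = 4.75e-06) and -0.81 (SE 0.08, adjusted p = 2.73e-06). Fabp7, a fatty acid binding protein of satellite glia, went from 404 ± 73.3 to 131 ± 8.43 CPM (-1.63, SE 0.11, adjusted p = 2.51e-08), and Camk2n1, an inhibitor of the kinase CaMKII, had a fold change of -1.25 (SE 0.08). Vash1, an inhibitor of vessel growth that also acts on tubulin, rose from 13 ± 4.36 to 76.5 ± 7.31 CPM. In all, 6313 genes passed, 3194 higher and 3119 lower, and 1488 changed at least 2-fold. With the mean of the spinal cord list of each library as a covariate, added after the data were seen, 36 genes passed.

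Cholesterol synthesis genes fell in 16 of 24 cases and rose in 1 (18 adjusted over the list alone), with a median of -0.44 (adjusted p = 2.27e-11, and adjusted p = 0.00887 with an estimated correlation). Msmo1 and Cyp51, demethylating steps of the pathway, had fold changes of -0.72 (SE 0.07) and -0.62 (SE 0.07). In the unfolded protein response list 8 of 25 fell and 2 rose (12 adjusted over the list alone; adjusted p = 0.0225, and adjusted p = 0.288 with an estimated correlation): the chaperone genes Calr (-0.66, SE 0.08) and Manf (-0.84, SE 0.1) fell while the sensor gene Ern1 rose by 1.33 (SE 0.2). Nuclear oxidative phosphorylation genes fell in 44 of 51 cases and rose in 0 (45 adjusted over the list alone; adjusted p = 1.26e-18, and adjusted p = 0.474 with an estimated correlation), with Cox6a1 and Cox8a of cytochrome c oxidase at -0.95 (SE 0.12) and -0.89 (SE 0.13). Cytosolic ribosomal protein genes fell in 64 of 69 cases and rose in 0 (69 adjusted over the list alone; adjusted p = 5.69e-27, and adjusted p = 0.474 with an estimated correlation), with a median of -0.67 and Rps29 at -1.1 (SE 0.18). Rps7, again uncertain, stood at -4.86 (SE 0.22), and summed with Gm6472 at 704 ± 82.4 CPM in wild types and 314 ± 28.7 CPM in mutants. With the spinal cord list mean as a covariate, the oxidative phosphorylation median went from -0.57 to -0.25 and the ribosomal median from -0.67 to -0.28, while the cholesterol median was -0.44 with and without it. With the covariate, 1 of the 24 cholesterol genes still passed lower.

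Some members of the glial and macrophage lists were lower at P0, though these lists lost their call with an estimated correlation. Myelinating Schwann cell genes fell in 11 of 26 cases and rose in 1 (14 adjusted over the list alone; adjusted p = 0.000959, and adjusted p = 0.646 with an estimated correlation), with a median of -0.6. Gjb1, the gap junction gene of myelin, had a fold change of -1.87 (SE 0.35). In the immature Schwann cell and satellite glia list 11 of 33 fell and 4 rose (16 adjusted over the list alone; adjusted p = 0.00707, and adjusted p = 0.288 with an estimated correlation); Gpr37l1 and Apoe had values of -1.48 (SE 0.18) and -0.91 (SE 0.13). Macrophage and immune cell genes fell in 14 of 31 cases and rose in 1 (15 adjusted over the list alone; adjusted p = 0.000644, and adjusted p = 0.572 with an estimated correlation), with the complement gene C1qa and the growth factor receptor gene Csf1r both at -1.06 (SE 0.13 and 0.14). Sensory neuron transcription factors rose in 21 of 49 cases and fell in 5 (31 adjusted over the list alone; adjusted p = 0.0221, and adjusted p = 0.474 with an estimated correlation), with a median of 0.34, or 0.28 with 2 members absent from a group at their bounds; Pou4f2 rose by 0.75 (SE 0.11) and Casz1 by 0.82 (SE 0.11). Peptidergic nociceptor genes fell in 8 of 23 cases and rose in 1 (10 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.474 with an estimated correlation), with the somatostatin receptor gene Sstr2 at -1.43 (SE 0.27).

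The spinal cord and central glia list fell in 24 of 32 cases and rose in 1 (28 adjusted over the list alone; adjusted p = 2.27e-11, and adjusted p = 0.16 with an estimated correlation), with a median of -2.18. Its mean level was 2.13 ± 0.16 log2 CPM in wild-type and 0.09 ± 0.74 in mutant P0 libraries. Olig1, an oligodendrocyte lineage factor, and Irx3, a patterning factor of the spinal cord, had fold changes of -3.38 (SE 0.43) and -2.07 (SE 0.27). Meningeal genes rose in 12 of 22 cases and fell in 0 (14 adjusted over the list alone; adjusted p = 6.77e-05, and adjusted p = 0.572 with an estimated correlation), with Aldh1a2, which makes retinoic acid, up by 2.02 (SE 0.42) and Slc6a20a by 1.91 (SE 0.34). Among the large decreases named by rule were those of Rec8 (-5.89, SE 0.79), Irx1 (-3.62, SE 0.42), the zinc transporter gene Slc30a3 (-3.61, SE 0.67, but 0.41 with adjusted p = 0.99 with the spinal cord covariate) and Sst, which encodes somatostatin, from 45.4 ± 11.3 to 3.73 ± 3.17 CPM. Kcnf1, a modifying potassium channel subunit, and Sned1, a matrix protein gene, rose by 2.29 (SE 0.28) and 2.54 (SE 0.51). Nr1d1, a repressor in the circadian clock, went from 41.8 ± 7.15 to 14.7 ± 2.05 CPM, and Odc1, the first enzyme of polyamine synthesis, from 94.5 ± 2.8 to 37.3 ± 2.24 CPM. Of Odc1, 31.3% of the sequence is shared with other genes, most with the pseudogene Gm7993, so its level is uncertain. Gm7993 stood at 0 to 0.0318 CPM in the wild types of E13.5 and P0 and at 1.42 to 3.61 CPM in all other libraries. The fall of Odc1 was not separated from a difference of those wild-type libraries. Of Slc6a20a, 32% is shared, most with Slc6a20b, so its value is uncertain too. Amd2, Gp1bb, Bglap, Hist2h2aa1 and the urinary protein gene Mup1 also met the rule, with 90.9%, 91.5%, 62.9%, 100% and 70.2% of their sequence shared with other genes, and are uncertain. At P0 all 3 mutants and wild type D carried Xist while wild types B and C carried Y-linked transcripts; against wild type D alone, with the other groups supplying its spread, 1596 genes passed.

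At P10 few genes differed between the libraries labelled wild type and mutant. All 3 labelled wild type and mutant 1 carried Xist, while mutants 2 and 3 carried Y-linked transcripts, so sex was partly tied to genotype. Rab3b, a vesicle-associated GTPase gene, rose from 30.4 ± 1.75 to 46.2 ± 5.27 CPM (0.6, SE 0.09, adjusted p = 0.0141), whereas Tfrc, the transferrin receptor gene through which cells take up iron, fell from 232 ± 36.4 to 132 ± 13 CPM (-0.81, SE 0.1, adjusted p = 0.00172). At P0 both lay the other way. Rab3b stood at 53.8 ± 3.74 CPM in P0 wild types and 32.5 ± 1.35 CPM in P0 mutants, Tfrc at 41.1 ± 2.33 and 69.5 ± 2.17 CPM. At E13.5 they stood at 21.7 ± 1.98 and 23 ± 1.08 CPM for Rab3b, and 44 ± 3.2 and 52.7 ± 1.93 CPM for Tfrc. Sorl1, a sorting receptor gene of endosomes, fell from 137 ± 19.6 to 82.1 ± 0.369 CPM (-0.74, SE 0.12, adjusted p = 0.0141). The library labelled wild type P10 1 held 197 CPM of Tfrc and those labelled C and E 229 and 270 CPM, against 118 to 143 CPM in mutants. For Sorl1 these were 115, 153 and 143 CPM, against 81.8 to 82.5 CPM. Both differences thus rest in part on the libraries whose label Tmem184b goes against. Rab3b stood at 32.1, 30.5 and 28.6 CPM, against 43.1 to 52.3 CPM in mutants. Hspa8, a chaperone gene, and Rnf26, a ubiquitin ligase gene, had fold changes of -0.9 (SE 0.11, adjusted p = 0.00172) and -1.05 (SE 0.14, adjusted p = 0.00309), but both share sequence with other genes. Summed with the pseudogenes Gm15459 and Gm26825, Hspa8 stood between 2810 and 3050 CPM in the libraries labelled wild type and between 2820 and 3000 CPM in mutants. Rnf26 summed with its copy Gm9008 stood lower in mutants, at 24.2 to 25.7 CPM against 34.8 to 53.7 CPM. However, 72.5% of its sequence is shared, most with Gm49380, which was not in the sum, so its value is uncertain. The 8 genes that passed, 3 higher and 5 lower, also hold Snora31, Gm40518 and Gm49384, and 1739 genes had an unadjusted p under 0.05.

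No gene list had a member called at P10 over all genes. Non-peptidergic nociceptor genes, markers of a class of skin-innervating pain and itch neurons, had a median of -0.29 over 26 members (6 adjusted over the list alone; adjusted p = 1.19e-11, and adjusted p = 0.537 with an estimated correlation). Pruriceptor and itch genes had a median of -0.21 over 28 members (0 adjusted over the list alone; adjusted p = 0.000138, and adjusted p = 0.537 with an estimated correlation). Their mean was 3.58 log2 CPM in the library labelled wild type P10 1, 3.86 and 3.91 in C and E, and 3.5 to 3.57 in mutants. For the non-peptidergic list these were 5.58, 5.88 and 5.98, and 5.43 to 5.51. Both shifts thus rest mainly on the libraries labelled C and E. Cd55 stood at -0.42 (SE 0.1, adjusted p = 0.358), Lpar5 at -1.26 (SE 0.4, adjusted p = 0.461) and Il31ra, an itch cytokine receptor gene, at -1.81 (SE 0.59, adjusted p = 0.469). Of Il31ra, the library labelled wild type P10 1 held 1.11 CPM, those labelled C and E 6.83 and 8.94 CPM, and the mutants 1.72, 1.94 and 1.12 CPM, so this difference rests on the libraries whose label Tmem184b goes against. Cytosolic ribosomal protein genes had a median of 0.22 over 69 members (0 adjusted over the list alone; adjusted p = 1.19e-11, and adjusted p = 0.764 with an estimated correlation). With the libraries labelled C and E left out, and the lone wild type assumed to vary like the other groups, 11 genes passed, 2 of them among the 8. Without the library labelled wild type P10 1, 290 genes passed.

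Averaged over the 3 ages, members of the cholesterol synthesis and unfolded protein response lists were lower in mutants and members of the synaptic vesicle and release list were higher. Cholesterol synthesis genes fell in 13 of 24 cases and rose in 0 (16 adjusted over the list alone), with a median of -0.16, and unfolded protein response genes fell in 9 of 25, rose in 2 and did not pass in 14 (11 adjusted over the list alone), with a median of -0.08. At P10 alone the directions were not shared by all: the cholesterol median was 0.06 and the synaptic vesicle median -0.07, and neither list was called (adjusted p = 0.339 and 0.117). Averaged over ages, the cholesterol and unfolded protein response lists kept their call with either correlation (adjusted p = 1.14e-08 and 3.01e-05, and both adjusted p = 0.0141 with an estimated correlation). Calr had a value of -0.43 (SE 0.05), the disulfide isomerase gene Pdia6 of -0.36 (SE 0.04) and Sdf2l1 of -0.59 (SE 0.08). Synaptic vesicle and release genes rose in 22 of 35 cases and fell in 0 (24 adjusted over the list alone; adjusted p = 8.36e-11, and adjusted p = 0.322 with an estimated correlation), Rims2 by 0.5 (SE 0.05). Odc1 (-0.84, SE 0.07, adjusted p = 1.87e-07), Fabp7 (-0.69, SE 0.06) and Prdm8 (1.11, SE 0.09) were among the genes with small p-values that met the naming rule, with the adhesion receptor gene Adgrd1 (1.39, SE 0.12). The calcium-binding protein gene Cabp7 and the thyroid hormone transporter gene Slco1c1 had values of -1.35 (SE 0.16) and -1.5 (SE 0.26). At P10 alone Odc1 stood at 30.4 ± 2.17 CPM in libraries labelled wild type and 28.6 ± 3.63 CPM in mutants. Fabp7 stood at 264 ± 12.7 and 251 ± 5.87 CPM, Prdm8 at 28.5 ± 6.1 and 33 ± 3.68 CPM. Adgrd1 stood at 7.19 ± 1.34 and 7.6 ± 0.164 CPM, Slco1c1 at 2.2 ± 0.412 and 2.11 ± 0.928 CPM. These averages thus rest mainly on E13.5 and P0, whereas Cabp7 stood at 31.6 ± 8.33 and 19 ± 1.57 CPM at P10. In all 4489 genes passed, 2487 higher and 2002 lower. With the libraries labelled wild type P10 C and E left out 4276 passed, 3432 of them shared, and over E13.5 and P0 alone 7800 passed, 4354 of them shared.

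Of the tested genes, 7755 were genes with a genotype effect that differs between ages (edgeR joint test). Tac1, Adcyap1, March4, Cemip, Fbln5 and Fam213a stood higher in mutants at E13.5 and lay closer between genotypes at P10. March4 went from 3.73 ± 0.652 to 25.4 ± 4.27 CPM at E13.5, from 39.9 ± 5.76 to 70.1 ± 6.43 CPM at P0 and from 25 ± 1.49 to 23.9 ± 0.698 CPM at P10. Gp1bb, a platelet glycoprotein gene that shares transcripts with Sept5, went from 45.7 ± 8.55 to 9.01 ± 0.992 CPM at P0. With the libraries labelled wild type P10 C and E left out, 4383 were genes with a genotype effect that differs between ages, and between E13.5 and P0 alone 4036 were.

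In wild types, members of the nociceptor and synaptic vesicle lists rose from E13.5 to P0 and members of the sensory neuron transcription factor list fell. Calca and Calcb, which encode the neuropeptide CGRP, rose by 8.22 (SE 0.15, adjusted p = 4.65e-18) and 5.72 (SE 0.24), and Tac1 from 1.89 ± 0.676 to 152 ± 4.52 CPM. Scn11a, a sodium channel gene of nociceptors, rose by 7.5 (SE 0.23), and Mrgprx1, without a read at E13.5, was at least 935-fold higher. The early neuronal factor genes Sox11, Nhlh2 and Neurod1 had values of -3.87 (SE 0.1), -4.61 (SE 0.16) and -6.06 (SE 0.23). In the lists, 21 of 26 non-peptidergic (23 adjusted over the list alone), 18 of 23 peptidergic (21 adjusted over the list alone) and 34 of 35 synaptic vesicle genes (34 adjusted over the list alone) rose, with 2, 3 and 0 lower and medians of 2.33, 1.34 and 1.5. These lists were called with both correlations (adjusted p = 1.03e-18, 1.09e-10 and 3.6e-21, and adjusted p = 0.0378, 0.00324 and 0.0378 with an estimated correlation). Sensory neuron transcription factors fell in 33 of 49 cases and rose in 8 (42 adjusted over the list alone; adjusted p = 4.62e-11, and adjusted p = 0.00436 with an estimated correlation). Pruriceptor and itch genes rose in 22 of 28 cases and fell in 1 (23 adjusted over the list alone; adjusted p = 1.09e-05, and adjusted p = 0.0572 with an estimated correlation). Myelinating Schwann cell genes rose in 24 of 26 cases and fell in 2 (26 adjusted over the list alone; adjusted p = 1.97e-09, and adjusted p = 0.203 with an estimated correlation), with Pmp22 up by 4.57 (SE 0.22). All 44 cell cycle genes fell (44 adjusted over the list alone; adjusted p = 3.12e-19, and adjusted p = 0.17 with an estimated correlation), with a median of -1.87. Of all genes, 12557 passed, 6541 higher and 6016 lower.

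From P0 to P10, the wild types gained itch receptor, myelin and sterol genes and lost matrix and ribosomal protein transcripts, though each list lost its call with an estimated correlation, as given below. Of the 3 P10 libraries, 2 have a doubtful label. Nppb, a natriuretic peptide gene of itch neurons, rose by 4.97 (SE 0.25, adjusted p = 3.07e-11) and the leukotriene receptor gene Cysltr2 by 3.83 (SE 0.34). Pruriceptor and itch genes rose in 23 of 28 cases and fell in 2 (25 adjusted over the list alone; adjusted p = 4.8e-12, and adjusted p = 0.0531 with an estimated correlation), and non-peptidergic nociceptor genes rose in 22 of 26 and fell in 2 (24 adjusted over the list alone; adjusted p = 3.52e-13, and adjusted p = 0.104 with an estimated correlation). Myelinating Schwann cell genes rose in 17 of 26 and fell in 2 (19 adjusted over the list alone; adjusted p = 0.000246, and adjusted p = 0.429 with an estimated correlation), with Drp2 up by 2.59 (SE 0.14). Cholesterol synthesis genes rose in 17 of 24 and fell in 0 (18 adjusted over the list alone; adjusted p = 5.58e-06, and adjusted p = 0.0718 with an estimated correlation), with Msmo1 up by 1.07 (SE 0.07). Fibroblast and extracellular matrix genes fell in 24 of 33 cases and rose in 2 (28 adjusted over the list alone; adjusted p = 5.07e-06, and adjusted p = 0.416 with an estimated correlation), with Postn at -2.15 (SE 0.2). All 69 ribosomal protein genes fell (69 adjusted over the list alone; adjusted p = 2.21e-25, and adjusted p = 0.378 with an estimated correlation), with a median of -0.96. Their mean went from 8.99 to 7.95 log2 CPM in wild types and from 8.27 to 8.17 in mutants. This comparison crosses the difference that sets the wild-type P0 libraries apart from the later ones. Of all genes 9493 passed, 4742 higher and 4751 lower. With the libraries labelled wild type P10 C and E left out 5335 passed, 5039 of them shared and in the same direction.

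Genotype effects were compared with normal development across the 21051 genes, which are not independent replicates. The E13.5 effect had a Pearson r of 0.207 (Spearman rho 0.177) with the wild-type change from P0 to P10, a change that shares none of its libraries. The P0 effect had an r of 0.104 (rho 0.0726) with the change from E13.5 to P10, and the P10 effect an r of -0.0112 with the change from E13.5 to P0. At 14 genes the 6 wild-type E13.5 and P0 libraries stood apart from all 12 others, the library labelled wild type P10 1 included. The E13.5 and P0 effects and the wild-type changes to P10 cross the same difference with the same sign and are therefore not independent. With mutant age changes in place of wild-type ones, chosen after the data were seen, r was -0.0684 at E13.5 and -0.0872 at P0. Among 9894 genes called at E13.5 or P0, 65.6% had the same sign at both ages. Of 2299 genes called at both, 1784 moved the same way, 874 higher and 910 lower, against 498 and 385 for independent lists. A difference shared by the wild types of both ages would also give calls in the same direction, so the independent values are not a full comparison. P10 effects had the same sign as the E13.5 effects for 36% of 5887 genes and as the P0 effects for 21.5% of 6316 genes.

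Genes near the trap were tested for a flanking chromosome effect. Within 10 Mb of Tmem184b, 105 of 334 genes passed at E13.5 and 27.9% of 20696 genes elsewhere (odds ratio 1.19, 95% interval 0.93 to 1.5, Fisher's exact p = 0.157, adjusted p = 0.209). The odds ratio was 1.25 at P0 (0.984 to 1.57, exact p = 0.062, adjusted p = 0.124) and 1.29 averaged over ages (0.991 to 1.65, exact p = 0.0507, adjusted p = 0.124). At P10 none of the 8 genes lay there. These 4 tests were two-sided and none passed.

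**Figure D3:**
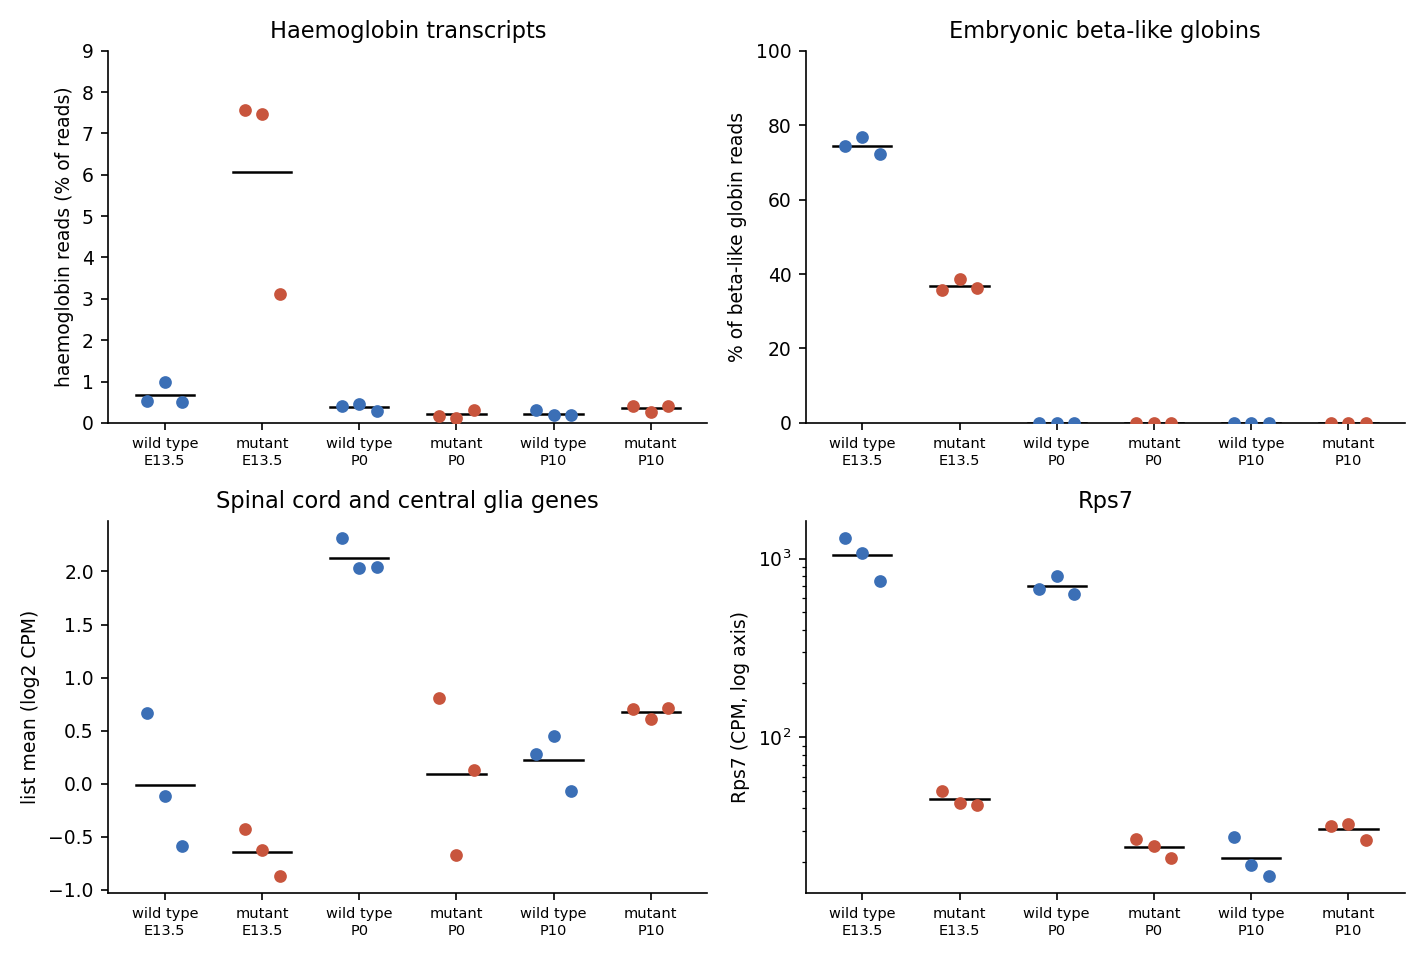
Measures of each library by genotype and age: haemoglobin transcripts in percent of reads, embryonic beta-like globins in percent of beta-like globin reads, the mean of the spinal cord and central glia list in log2 CPM, and Rps7 in CPM on a log axis. Points are libraries and lines are group means. Haemoglobin averaged 6.06% in E13.5 mutants and 0.673% in E13.5 wild types, and the spinal cord list averaged 2.13 in P0 wild types and 0.09 in P0 mutants.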

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

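Except for the average over ages, values here come from the joint test of whether the genotype effect differs between the 3 ages. Groups of 3 are too small for a test of a single library that stands apart. In edgeR, 7755 genes differed in their genotype effect between ages. Among genes that met the naming rule, the smallest adjusted p-values belonged to Rps7 (6.06e-09), March4 (1.64e-07), Adcyap1 (6.91e-07), Gp1bb (9.51e-07), Fbln5 (1.03e-06), Cemip (1.03e-06), Tac1 (1.03e-06) and Fam213a (1.12e-06). Of 100 groupings of the libraries, the real one included, 1 gave as many genes, the real one itself, and the highest other gave 4105. The groupings shuffled genotype within each age and so also broke up any effect common to the ages. They therefore cannot exclude chance for a difference between ages, and 2 of the P10 libraries have a doubtful label. For the average over ages, 1 of 100 groupings, the real one, gave 4489 genes and the highest other gave 2417. A count that large was rare among random groupings, which does not separate genotype from library source.

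For the single comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each of the 5 comparisons 1 split, the real one, gave the real count, with the highest other in second place: 5880 and 2 genes at E13.5, 6313 and 0 at P0, 8 and 1 at P10, 12557 and 1 for wild type P0 against E13.5, and 9493 and 0 for wild type P10 against P0. Of the correlations with maturation, the real value and the highest other in size were 0.207 and 0.155 at E13.5, 0.104 and 0.088 at P0, and -0.0112 and 0.0275 at P10, where 7 of 10 splits were as large.

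In the 3 patterns that follow, the tests of library source, sex, muscle and blood, and all 3 tests of the P10 labels were chosen after the result was seen. Many genes passed at E13.5 and P0 and few at P10, and sex alone is argued against, since with Y-linked expression as a covariate in all libraries the genes changed, mutant against wild type at E13.5, were 4043, and the genes changed, mutant against wild type at P0, were 4440. Libraries of one sex gave 1336 and 1596, each from a lone library, of which mutant E13.5 3 also held 8.91 CPM of Xist. A difference of source or library making carried by the 6 wild types of these ages remains open: 14 genes set them at least 4-fold apart from all 12 other libraries, the wild-type library P10 1 among them, against 0 for the 6 mutants of these ages. Among the 14, Rps7 stood at 636 to 1310 CPM against 16.8 to 50.1, and its copy Gm6472 at 0 to 0.499 CPM against 158 to 500. A lasting effect of the trapped gene cannot be told apart from this, since it rests on a single P10 library: of 1784 genes called alike at E13.5 and P0, 43.7% had that direction in it.

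Mutant E13.5 ganglia had higher channel and synaptic genes and lower cell cycle genes. Muscle and blood in the mutant samples would dilute neuronal transcripts, yet the pan-neuronal median was 0.34. For spinal cord tissue in the wild types, the cell cycle median was -0.71 with that list as covariate and -0.81 without. The covariate had a single slope per gene, fitted to the spread within groups of all ages. That slope need not match the cell cycle genes of E13.5 spinal cord, so this test cannot decide and spinal cord tissue remains open. A later stage of the mutant embryos is consistent with globin switching, as embryonic forms made up 36.8% of beta-like globin reads in mutants and 74.4% in wild types without overlap, which chance gives in 10% of cases for 3 against 3. An earlier neuronal maturation through the loss of Tmem184b stays open as an untested hypothesis beside it.

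The libraries labelled wild type P10 C and E had low Tmem184b. An exchange with mutant libraries would leave a mutant library at the wild-type level, and the highest P10 mutant held 3.33 CPM. Heterozygous animals would keep a large part of the transcript, and the higher of the 2 libraries held 8.01% of the wild-type mean. Mutants of the same group under a wrong label remain open. The 290 genes called between these 2 libraries and the 3 mutants cannot decide this, since sex differed too. C and E carried Xist, whereas mutants 2 and 3 carried Y-linked transcripts. How many genes such sets of libraries of the same genotype would give is not known. Mutant animals of another litter or source remain open and were not tested.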

How the results depend on the processing

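Settings that used libraries of one sex, left out the libraries labelled wild type P10 C and E, used E13.5 and P0 alone, took mutant age changes or a spinal cord covariate were chosen after the data were seen. With TMM and RLE scaling the list directions were the same. Counts of genes changed moved by over 1.5 times as follows. With libraries of one sex, 1336 genes passed at E13.5, 1596 at P0 and 0 at P10 (edgeR; 1739 at an unadjusted p with all libraries), where fewer libraries were compared. The spinal cord covariate left 36 genes at P0: the median size of effects went from 0.57 to 0.38 and the median SE from 0.13 to 0.25, with 96.4% of signs kept. At P10 the count was 29 with no low-count filter, 5 with a stricter filter, 2 with length offsets, 47 in DESeq2, 3 with Y-linked expression as a covariate and 13 with P10 libraries alone. The average over ages gave 7800 genes over E13.5 and P0 only. The genes with a genotype effect that differs between ages numbered 4108 with the Y-linked covariate, 4383 with the libraries labelled wild type P10 C and E left out and 4036 with E13.5 and P0 only. Wild type P10 against P0 gave 5335 with C and E left out. Causes other than fewer libraries were not tested.

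The Tmem184b log2 fold change at E13.5 was -2.62 (adjusted p = 0.0521) and the Tmem184b log2 fold change at P0 was -2.08 (adjusted p = 0.0896) with length offsets; they were -4.68 (adjusted p = 0.184) and -4.26 (adjusted p = 0.0782) with one sex. The value was -3.9 (adjusted p = 0.604) at P0 with the spinal cord covariate, and -4.98 (adjusted p = 1.53e-09) at P10 with C and E left out. Over its alternatives the adjusted p ran from 2.64e-06 to 0.184 at E13.5, from 3.59e-08 to 0.604 at P0 and from 1.53e-09 to 1 at P10. DESeq2 gave 16 tested genes no adjusted p at E13.5, Tmem184b among them. Slc30a3 at P0 turned to 0.41 (adjusted p = 0.99) with that covariate. Of 4255 alternative values of 242 named effects, 3959 kept direction and side, 289 lost and 6 gained their call, and 1 reversed. With an estimated correlation camera called 1 list at E13.5, 1 at P0, 0 at P10, 2 averaged over ages, 7 for wild type P0 against E13.5 and 0 for wild type P10 against P0. The planned fry test, which does not set a list against other genes, called 22, 20, 0, 24, 34 and 35 lists in the same order. At E13.5 the fry adjusted p was 2.4e-05 for the channel list, 1.47e-05 for the synaptic list and 0.000207 for the cell cycle list. Correlations with mutant age changes were -0.0684 at E13.5 and -0.0872 at P0, and the P10 value was -0.0444 for genes with an average log2 CPM of at least 3. With the Y-linked covariate 43.7% of genes kept their sign between E13.5 and P10.

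Leaving out each library in turn gave 4213 to 6867 genes at E13.5, 4398 to 6245 at P0, 3574 to 6199 averaged over ages, 6460 to 8640 that differed between ages, 11719 to 12333 for wild type P0 against E13.5 and 8004 to 9253 for wild type P10 against P0. At P10 the range was 4 to 290: 290 without wild type P10 1, 5 without the library labelled C or E, 17 without mutant 1 and 4 without mutant 2. Tmem184b ranged from -5.33 to -4.97 at E13.5, -4.42 to -4.14 at P0, -4.09 to -0.26 at P10 (-0.26 without wild type P10 1) and -4.49 to -3.22 averaged. The maturation correlation ranged from 0.168 to 0.214, 0.0814 to 0.112, and -0.0303 (without wild type P10 1) to 0.00502 (without mutant P10 3).

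No paired analysis was possible because the genotypes share fewer than 2 replicate names at any age. Of genes changed, wild type P0 against E13.5, a block of letters B and C gave 9405 and the same 4 libraries without the block 9502; the deviations of the letters correlated at 0.0738 and -0.384, so the libraries share only a letter.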

Other observations

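The genes of this part were taken from lists fixed before the data were examined, and the chromosome 9 count, the Hspa8 sums and the P10 comparisons with library 1 or with C and E were chosen after the result was seen. At E13.5, members of 2 further lists of channel and signalling genes were higher in mutants, though both lists lost their call with an estimated correlation. Calcium channel and transient receptor potential genes rose in 14 of 31 cases and fell in 0 (17 adjusted over the list alone; camera adjusted p = 5.1e-07, and adjusted p = 0.0974 with an estimated correlation), with Piezo2, the touch channel gene, up by 1.17 (SE 0.16) and Asic3, an acid-sensing channel gene, up by 1.43 (SE 0.1). Neurotrophin and GDNF-family signalling genes rose in 9 of 24 cases and fell in 1 (10 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.179 with an estimated correlation), with the co-receptor gene Gfra3 up by 0.67 (SE 0.11). Notch pathway genes fell in 8 of 25 cases and rose in 4 (15 adjusted over the list alone; adjusted p = 0.00586, and adjusted p = 0.398 with an estimated correlation), among them the target gene Hes5 at -1.86 (SE 0.3) and the ligand gene Dll3 at -2.32 (SE 0.29).

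Some Hox genes, which mark position along the body axis, differed at both ages. The axial levels of the ganglia taken are not given in the sources used here, so a difference in levels between groups was not ruled out for these or other genes. At E13.5 Hoxb4 (-1.08, SE 0.15) and Hoxc6 (-1.06, SE 0.19) were lower and 10 of 36 members fell while 2 rose (12 adjusted over the list alone; adjusted p = 0.00586, and adjusted p = 0.441 with an estimated correlation). At P0 15 fell and 4 rose (19 adjusted over the list alone; adjusted p = 0.0225, and adjusted p = 0.646 with an estimated correlation): Hoxa4 and Hoxa5, of anterior levels, had values of -1.66 (SE 0.19) and -1.53 (SE 0.17), while Hoxa9, of posterior levels, rose by 1.08 (SE 0.14). The spinal cord list also differed at P0, at 2.13 ± 0.16 log2 CPM in wild types and 0.09 ± 0.74 in mutants. Adipocyte genes rose in 7 of 18 cases at P0 and fell in 0 (7 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.646 with an estimated correlation), and cartilage and bone genes fell in 11 of 28 and rose in 0 (11 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.646 with an estimated correlation), with the bone phosphatase gene Alpl at -0.95 (SE 0.13).

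Of the 100 genes with the smallest p at P10, 21 lay on chromosome 9, which holds 5.85% of tested genes (Fisher's exact adjusted p = 5.21e-06 over 20 chromosomes), 16 of them between 35 and 56 Mb of GRCm38. With library 1 against the mutants 21 of the 100 lay on chromosome 9 (adjusted p = 4.6e-06), and with the libraries labelled C and E against the mutants 10 did (adjusted p = 0.949). Hspa8, Sorl1 and Rnf26 lie in that interval. The pseudogenes Gm15459 and Gm26825, which share sequence with Hspa8, together held 1.81 and 1.84 CPM in the libraries labelled wild type P10 1 and C, 958 CPM in that labelled E, 1430 to 1520 CPM in P10 mutants and 672 to 708 CPM in P0 mutants, with 1.54 to 3.93 CPM in all E13.5 and wild-type P0 libraries.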
